A study of Mus musculus with 20 samples.

How the data were processed

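The study measured ribosome-bound mRNA and total RNA in C57BL/6 mouse oocytes over meiotic resumption. Per the labels, 3-week-old females received 5 IU of PMSG, oocytes were taken 44 h later and held with 1 µM cilostamide, and 200 oocytes were collected per sample at 0, 2, 4, 6 or 8 h. RNA was extracted with RNeasy Plus Micro columns. The description field of the total RNA samples also calls them ribosome-bound, whereas their titles and the series design name them input or total RNA; the titles and design were followed. Whether poly(A) RNA was selected and whether libraries kept strand are not given in the sources used here, so a change in tail length, which would alter recovery with poly(A) selection, stays open for both kinds of library.

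The authors' tool list names FastQC, Trimmomatic 0.36, HISAT2, SAMtools, HTSeq, edgeR and limma, with mm10 as the genome. The deposited values are a signal in scaled CPM, each library's CPM times a factor of its own, in 1 table for ribosome-bound mRNA and 1 for total RNA. Totals per library ran from 968768 to 1052767, and 10 of 20 exceeded the most that plain CPM can sum to. The plan had assumed plain CPM; the same test on the log2 values was kept. In every library 100% of values were whole multiples of a single step, within 0.01 of a read. From these steps the depth was inferred as 27571236 to 51714900 reads in listed genes per library, and a value of 10 stood for 282 to 533 reads. Differences between replicates exceeded counting error in each group (chi-square per degree of freedom 48.6 to 154), and no 2 libraries were counted as 1. The tables list only genes above a minimum, whose rule is not stated; every listed gene reached 10 in at least 1 library.

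Groups were taken from the sample labels, with letters A and B as replicates 1 and 2. All 20 libraries were used. Values were taken as log2 with a pseudocount of 1, for genes with a value of 1 in at least 2 libraries, which kept all 7543 genes of the ribosome-bound table and all 7917 of the total RNA table. A linear model over all times was fitted per RNA kind in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and a mean-variance trend. The threshold was a Benjamini-Hochberg adjusted p of 0.05 within each comparison. Comparisons were each time against 0 h in both RNA kinds, and neighbouring times on ribosomes. The ribosome-bound change beyond total RNA was the interaction of RNA kind and time over the 7346 genes in both tables. Tests were two-sided. All comparisons, lists, the naming rule and the alternatives were fixed before the data were examined, except those stated as added.

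Gene lists covered M-phase entry, the anaphase-promoting complex, spindle checkpoint and kinetochore, spindle and cytokinesis, cohesin and condensin, replication licensing, deadenylation and decay, and oocyte RNA-binding regulators. Others covered initiation and elongation factors, cytosolic ribosomal proteins, oxidative phosphorylation, the proteasome, the endoplasmic reticulum, zona and secreted factors, maternal-effect genes and chromatin. The last of the 21 were a list of genes described in earlier literature as translationally activated in oocyte maturation, markers of granulosa cells and of blood, stroma and endothelium, stress genes, and mitochondrially encoded transcripts. The literature list was written from general knowledge of the field and not from these samples; it shares genes with other lists. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation; p-values were adjusted over the lists of a comparison.

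Genes are named by a rule. For the 8 h comparisons it takes the 6 largest changes each way among genes past the threshold with a mean value of at least 20 and no overlap between the groups' libraries, leaving out unnamed gene models. It adds up to 2 members of each list per direction with the smallest p, and a fixed panel of 12 genes, of which Cnot7 is in neither table. For other comparisons it takes the 3 largest each way. Genes named outside the rule (Smc4, Zp1 and Slbp at early times, and genes moving in opposite directions) were chosen after their values were seen, as were Rps4x, Sdhd, Fubp3 and Obox5 as examples of shared change.

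Coordinates, transcript lengths, GC content and 3' UTRs came from GENCODE vM21, matched by gene ID: 5839 of 8114 IDs had the same version, 2264 another version and 11 were not found. For 2 symbols the tables hold 2 separate IDs. The model, the list test, the step of 1 read, the matched sets and the stratified motif difference were tested on simulated data; the other tests of the closing section were not. With 100 genes changed by a log2 of 1, limma recovered 47% on ribosomes, 58% in total RNA and 31% beyond total RNA. For another 100 genes in the same runs, changed by a log2 of 1.5, it recovered 74%, 89% and 66%. False calls were 3 of 124, 11 of 158 and 2 of 99, and 5 of 5 shifted lists and 0 of 5 unshifted lists were called in each. Genes were simulated independently of each other, so the list result does not cover false calls from correlation between genes. These runs had far fewer calls than the 3173 on ribosomes and 1543 beyond total RNA at 8 h. The adjusted threshold was thus stricter in them, and their recovery does not describe those comparisons.

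Alternatives were pseudocounts of 0.25 and 5, no filter, a minimum of 10, centring on library medians, no mean-variance trend, a 2-fold threshold, fits with only the compared times, a replicate block, an estimated correlation, and leaving out each library in turn. Added later were voom weights on the inferred reads, a minimum mean value of 20, and a correction of each library for transcript length and GC content (splines with 4 degrees of freedom), for lists before 8 h an estimated correlation, and leaving out each library for lists and named genes before 8 h and for the genes moving in both RNA kinds. The planned count-based tests in edgeR and DESeq2 were not run, since they need whole read counts and these are only inferred here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.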

Results

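Oocytes stop transcribing before they resume meiosis, so the proteins of the first division are made from stored transcripts, and which of these are on ribosomes can change without any new RNA. The samples came from mice whose oocytes carry an HA tag on a ribosomal protein (RiboTag, switched on by Zp3-Cre). Ribosomes were pulled down through the tag to give ribosome-bound mRNA, and total RNA was taken alongside. Each sample held 200 oocytes, collected at 0 h (prophase I), 2 h (early prometaphase I), 4 h (mid prometaphase I), 6 h (late prometaphase I) or 8 h (metaphase I) of culture after release from cilostamide, a phosphodiesterase inhibitor that holds oocytes in prophase. There were 20 libraries, 2 in each of the 10 groups made by RNA kind and time. The depth inferred for the listed genes ran from 27571236 to 51714900 reads per library. The ribosome-bound table listed 7543 genes and that of total RNA listed 7917, of which 7346 were in both. Replicates correlated across genes with a Pearson r between 0.949 and 0.974. On principal components, the ribosome-bound libraries lay in order of time on the axis holding 49.1% of their variance. On the next axis (12.5%), 4 h replicate 1 stood apart at -35.2, with the next lowest library at -4.88. The total RNA libraries spread less by time (28.4% on the leading axis), and their 8 h replicates lay at 20.2 and -25.0 on the next. The labels do not say whether replicates were separate cultures or animals, so p-values here measure only the spread between these samples.

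Many mRNAs differed in their share of the ribosome-bound fraction between prophase I and metaphase I. This comparison asks which transcripts rose and fell in the ribosome-bound fraction between release from arrest and the first metaphase. Transcripts for cyclin B1, MOS, BTG4, DAZL and tissue plasminogen activator rose. The lists of spindle, kinetochore and mRNA decay genes rose at a preset correlation between genes, but with an estimated correlation their adjusted p was 0.188, 0.126 and 0.113. Ribosomal protein, respiratory chain and proteasome genes fell as lists, with an adjusted p of 0.188, 0.0415 and 0.0944 with an estimated correlation. In limma, 3173 of 7543 genes passed an adjusted p of 0.05 at 8 h against 0 h, 1525 up and 1648 down, and 1866 of them changed at least 2-fold. The median change of all genes was -0.06 on the log2 scale. Once libraries were centred on their medians, 1677 genes were up and 1487 down, so the larger direction turned. A correction for transcript length and GC content gave 2732 genes (1387 up, 1345 down). Of these, 2243 were also called in the same direction without it. Values after ± on log2 changes are limma standard errors, with 2 libraries per group.

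**Figure D1:**
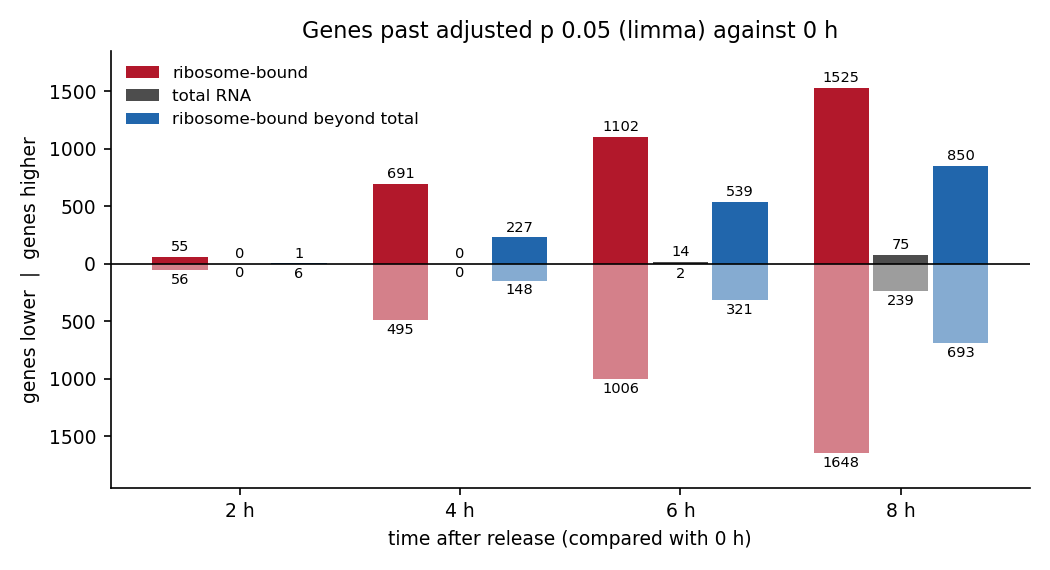
Genes past an adjusted p of 0.05 (y axis, number of genes, up above 0 and down below) at each time against 0 h (x axis, hours), for ribosome-bound mRNA, total RNA and the ribosome-bound change beyond total RNA. Ribosome-bound calls run from 111 at 2 h to 3173 at 8 h, and total RNA calls from 0 at 2 h to 314 at 8 h.

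Cyclin B1, the partner of CDK1, had the clearest rise among the cell-cycle regulators. Its transcript Ccnb1 (ENSMUSG00000041431.16, protein coding, mm10 chromosome 13, 100778650 to 100786570) went on ribosomes from a normalised value of 95.5 ± 10.7 (SD, n = 2) at 0 h to 511.6 ± 53.1 at 8 h, a log2 change of 2.41 ± 0.15 (adjusted p 4.4e-09). Plat, the tissue plasminogen activator (ENSMUSG00000031538.6, chromosome 8, 22757727 to 22782844), rose by 2.22 ± 0.17, from 1011 ± 259 to 4629 ± 141. Btg4, which recruits the deadenylase to maternal mRNA (ENSMUSG00000032056.9, chromosome 9, 51060901 to 51119875), rose by 1.88 ± 0.14. Dazl, an RNA-binding translational activator, rose by 1.88 ± 0.15, and the MAPK activator Mos by 1.76 ± 0.17. Among activators and substrates of the anaphase-promoting complex and the spindle, Cdc20 rose by 1.27 ± 0.21 and Tpx2 by 0.84 ± 0.14. Wee2 (0.45, adjusted p 0.014) and Ccnb3 (0.54, adjusted p 0.025) rose less. Wee2 no longer passed without 8 h replicate 1 (0.34) or without 0 h replicate 2 (0.35), and Ccnb3 without 0 h replicate 2 (0.39) or without 8 h replicate 2 (0.44). A correction for transcript length and GC content also ended both calls, with Wee2 at 0.26 (adjusted p 0.157) and Ccnb3 at 0.04 (adjusted p 0.873). Ccnb2 did not change detectably (0.06, adjusted p 0.86), and its sign turned without 0 h replicate 1 (-0.03) or without 8 h replicate 1 (-0.11). Cpeb1, which binds the cytoplasmic polyadenylation element, fell by 0.65 on the log2 scale (adjusted p 0.0013). A list of genes that earlier literature reports as translationally activated in oocyte maturation had 19 of 24 members up and 3 down (19 and 4 adjusted over the list alone). Its median was 1.25, with a camera adjusted p of 9.89e-08 and, with an estimated correlation between genes, an adjusted p of 0.0286. Zp2 and Zar1, both on that list, fell by 1.92 and 1.40 on the log2 scale.

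**Figure D2:**
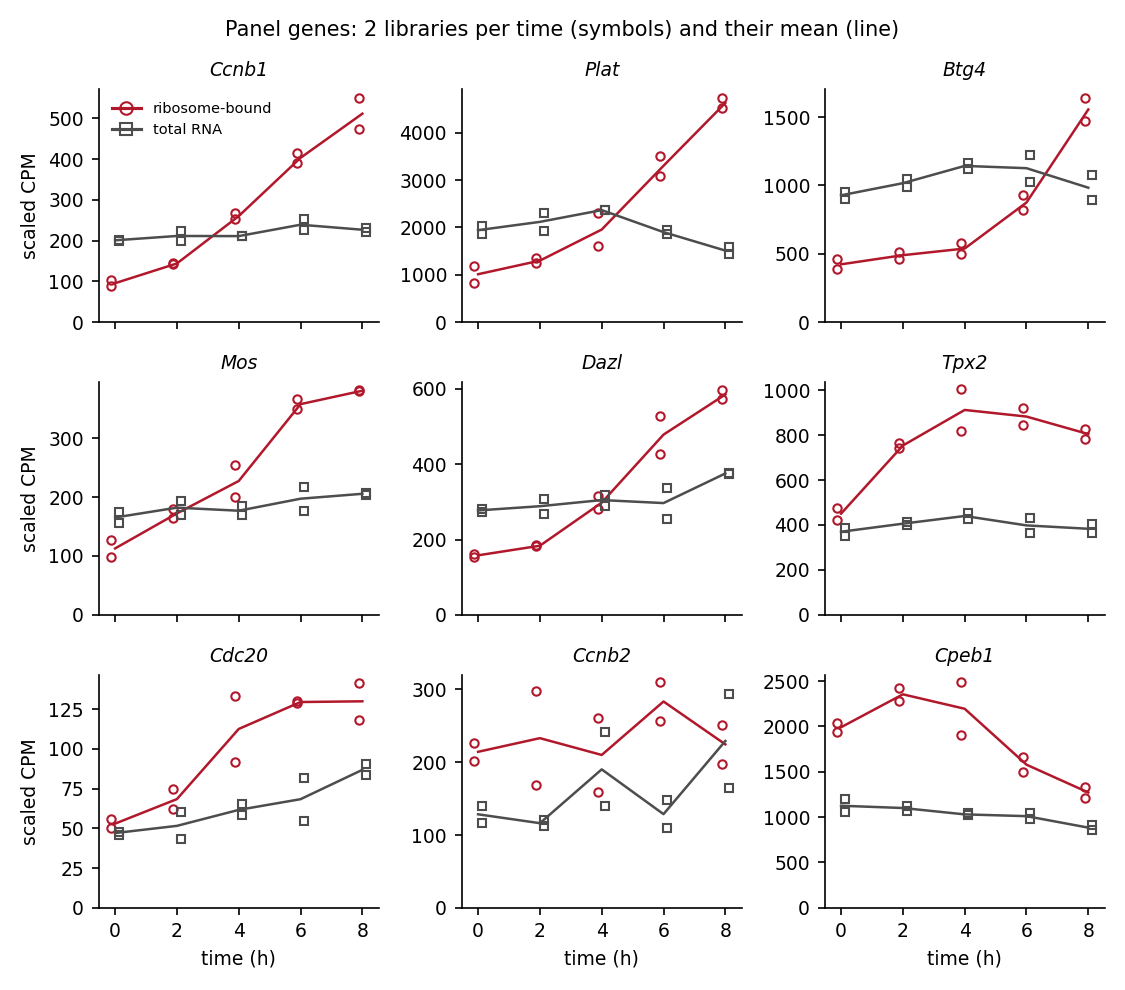
Normalised value (y axis, linear scale) against hours after release (x axis) for 9 genes in ribosome-bound mRNA and total RNA. Symbols are single libraries and lines join group means. Ccnb1 on ribosomes runs from a mean of 95.5 to 511.6, while in total RNA it stays between 200.8 and 239.1.

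Largest changes are ranked throughout among genes past the threshold with a mean value of at least 20 and no overlap between the groups' libraries, leaving out unnamed gene models. Under that rule the largest rises on ribosomes beyond the panel were in Fubp3 (3.18 ± 0.26), the exon junction gene Magoh (3.10 ± 0.23) and the centromere cohesin protector Sgol2a (2.72 ± 0.31). Next came 3 oocyte genes, the ubiquitin ligase subunit Rfpl4 (2.68 ± 0.15), Tcl1 (2.63 ± 0.15) and the homeobox gene Obox5 (2.63 ± 0.20). Magoh (ENSMUSG00000028609.6, chromosome 4, 107879755 to 107887424) went from 20.5 ± 8.68 to 176.6 ± 8.82, and Fubp3 (ENSMUSG00000026843.15, chromosome 2, 31572651 to 31617526) from 11.9 ± 1.75 to 115.3 ± 1.88. The largest falls under it were in the ATP synthase subunit Atp5e (-3.70 ± 0.39), Preb (-3.28 ± 0.73), Park7 (-3.26 ± 0.39), the ribosomal proteins Rps4x (-3.23 ± 0.35) and Rps13 (-3.17 ± 0.40), and the autophagy gene Map1lc3a (-2.93 ± 0.38). Preb moved to -1.27 without 0 h replicate 1 and to -5.28 without 0 h replicate 2. After the length and GC correction, Atp5e stood at -2.05 and Rps13 at -1.98.

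Genes that build and watch the spindle rose as lists at the preset correlation, but with an estimated correlation the adjusted p was 0.188 for spindle, 0.126 for kinetochore and 0.30 for cohesin and condensin genes. The spindle and cytokinesis list had 16 of 28 genes up and 3 down (median 0.50, camera adjusted p 0.00929), led by the kinesin Kif18a (2.23) and anillin, Anln (1.58), while Tacc3 fell by 2.01 on the log2 scale. The spindle checkpoint and kinetochore list had 13 of 28 up and 5 down (median 0.40, adjusted p 0.0304), with Ndc80 (1.80) and Bub1b (1.33) up and Birc5 (-1.44) and Spc25 (-1.65) down. Cohesin and condensin genes had 10 of 22 up and 4 down (median 0.38, adjusted p 0.0399). Wapl (1.70) and Ncapg2 (1.74) rose, while the condensin core gene Smc4 went from 2724 ± 94.1 to 602.9 ± 68.3 (-2.18). That list's call was lost without 0 h replicate 2 (adjusted p 0.0807) and without 8 h replicate 2 (adjusted p 0.0639). For these lists the counts adjusted over the list alone were the same. M-phase entry genes did not move as a group, with 10 of 24 up and 4 down (10 and 5 adjusted over the list alone; camera adjusted p 0.168). Cdk1 fell by 2.20 on the log2 scale and Mapk3 by 1.35, opposite to Ccnb1 and Mos. Genes of the anaphase-promoting complex split, 5 of 20 up and 9 down, with Cdc27 (1.81) and the inhibitor Fbxo43 (1.74) up and Anapc7 (-2.11) and Fzr1 (-1.23) down. Replication licensing genes split evenly, 9 of 28 each way, with Orc6 (2.19) and Mcm4 (1.96) up and Rpa2 (-2.40) down. In both of these lists the counts adjusted over the list alone were the same, and the camera adjusted p was 0.80 and 0.884.

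The transcripts that fell together encode the machinery of protein synthesis, respiration and protein breakdown. Cytosolic ribosomal protein genes fell in 38 of 48 cases and rose in 1 (43 and 1 adjusted over the list alone), with a median of -1.79 and a camera adjusted p of 2.09e-12; with an estimated correlation the adjusted p was 0.188. Rpl5 went from 254.0 ± 2.69 to 65.0 ± 6.12 (-1.95 ± 0.16) and Rps4x (ENSMUSG00000031320.9, chromosome X, 102184941 to 102189394) from 40.1 ± 2.37 to 3.39 ± 0.0853. Values of ribosomal protein genes are uncertain because reads can be shared with their many pseudogene copies. The single rise, Rps27l (1.86), was lost without 0 h replicate 1 (1.67), without 8 h replicate 1 (1.82) or without 8 h replicate 2 (1.89), and stood at 1.13 with a pseudocount of 5. Oxidative phosphorylation genes fell in 46 of 59 cases with no rise (50 adjusted over the list alone), with a median of -1.55, a camera adjusted p of 4.74e-13 and an adjusted p of 0.0415 with an estimated correlation. Atp5a1 fell by 2.06 on the log2 scale. Proteasome genes fell in 20 of 32 cases and rose in 3, the same adjusted over the list alone (median -1.20, camera adjusted p 0.000197). Psmc3 (-2.52) and Psmc2 (-2.22) fell, Psma2 rose (1.41), and with an estimated correlation the list's adjusted p was 0.0944. Initiation and elongation factor genes fell in 25 of 50 cases and rose in 4, again the same adjusted over the list alone (median -0.51, adjusted p 0.000489, and 0.0415 with an estimated correlation). Eif1ax (-1.94) and Eif3c (-1.24) fell, whereas Eif2b1 rose (0.85).

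**Figure D3:**
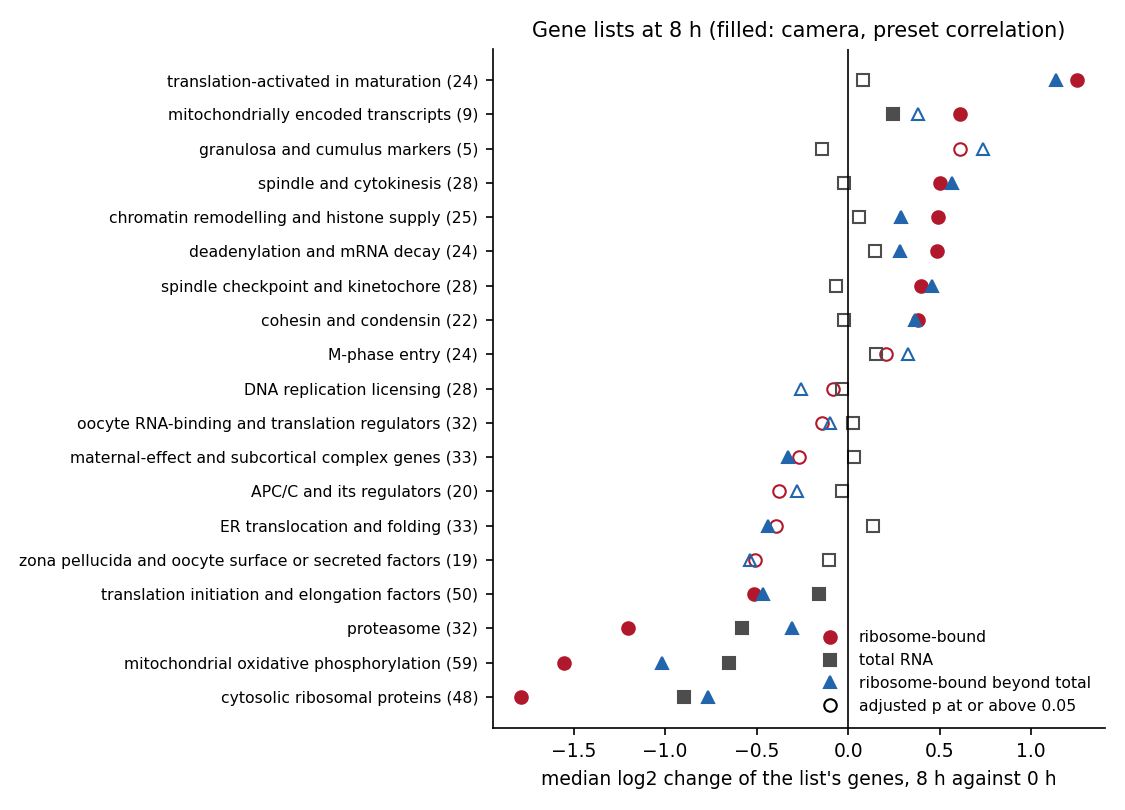
Median log2 change at 8 h against 0 h (x axis) of each gene list (y axis) in ribosome-bound mRNA, total RNA and the ribosome-bound change beyond total RNA; filled symbols have a camera adjusted p below 0.05. Ribosomal protein genes have a median of -1.79 on ribosomes and -0.90 in total RNA, while the literature list stands at 1.25 on ribosomes and 0.08 in total RNA.

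Among mRNA regulators, the deadenylation and decay list rose, with 11 of 24 up and 4 down (median 0.49, camera adjusted p 0.0116; with an estimated correlation, adjusted p 0.113). Pan2 (1.87) rose beside Btg4, while the scaffold Cnot1 fell by 0.89 on the log2 scale and Cnot10 by 1.51. Oocyte RNA-binding genes split, 8 of 32 each way (adjusted p 0.628): the poly(A) polymerase Papd4 rose (1.61) and Pabpc1l (-1.79) and Ybx2 (-1.36) fell. Both lists had the same counts adjusted over the list alone. Chromatin and histone supply genes rose in 13 of 25 cases and fell in 4 (16 and 5 adjusted over the list alone; median 0.49, camera adjusted p 0.00937, and an adjusted p of 0.245 with an estimated correlation). Slbp, which binds histone mRNA, rose by 2.16 and H3f3b by 1.51, while Hdac2 (-1.42) and Kdm1b (-1.30) fell.

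Genes for the egg coat and secreted proteins moved apart. Of 19 zona and surface genes, 6 rose and 11 fell, the same adjusted over the list alone (camera adjusted p 0.628; median -0.51, mean 0.05). Zp3 fell from 7122 ± 1714 to 1490 ± 246 (-2.24), and Zp2 by 1.92 on the log2 scale, whereas Oosp1 (2.62) and Oosp3 (2.31) rose. Maternal-effect genes had 8 of 33 up and 16 down, the same adjusted over the list alone (adjusted p 0.099), with Npm2 (-1.82) and Uhrf1 (-1.25) down; without 0 h replicate 2 the list's adjusted p was 0.0238. Endoplasmic reticulum genes had 5 of 33 up and 14 down (7 and 15 adjusted over the list alone; adjusted p 0.12, or 0.0405 without 0 h replicate 1). The chaperones Calr (-1.89) and Pdia3 (-1.47) fell, and Ssr3 (2.16) and Dnajc3 (1.18) rose.

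Markers of other cells and of handling were few in the ribosome-bound table. Of 5 granulosa and cumulus genes, Serpine2 (111 to 369, log2 change 1.74) and Cyp19a1 (34.0 to 85.5, 1.31) rose, the same adjusted over the list alone. The list had an adjusted p of 0.0614, or 0.0302 without 0 h replicate 1. Of the blood, stroma and endothelium list only Pecam1 and Tek were present, too few to test. Of 4 stress genes, also not tested as a list, Dnajb1 (-1.83) and Hsph1 (-1.10) fell; Dusp1 rose (1.31) but not past the threshold without 0 h replicate 2 (0.50). Mitochondrially encoded transcripts made up 0.100% of the ribosome-bound total at 0 h and 0.199% at 8 h, against 2.68% and 2.60% of total RNA. As a list they rose on ribosomes (4 of 9 up, the same adjusted over the list alone; adjusted p 0.0399), but with an estimated correlation the adjusted p was 0.475, without 8 h replicate 1 it was 0.504, and without 0 h replicate 2 it was 0.177. That replicate 1 held 0.272% and replicate 2 0.126%.

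At earlier times the same comparison asks when the change on ribosomes begins. A small set of genes passed by 2 h, with Tpx2 from the panel among them, and most of the panel followed at 4 h or 6 h. Magoh, Slbp and Tpx2 were early risers, and Eif5b and the condensin gene Smc4 were early fallers. At 2 h, 111 genes passed, 55 up and 56 down, or 80 up and 50 down once libraries were centred on their medians. The 2 h count was 171 (122 up, 49 down) without 0 h replicate 1, 16 without 2 h replicate 1 and 15 without 2 h replicate 2. Magoh (1.52), Dctd (1.43) and H2afx (1.36) rose most, and Eif5b (-1.72), Htatsf1 (-1.51) and Nomo1 (-1.51) fell most; Tpx2 also rose (0.74, adjusted p 0.011). Smc4 fell by 1.35 on the log2 scale and Zp1 by 1.35. Without 2 h replicate 2, Magoh (1.47), Dctd (1.15), Nomo1 (-1.66) and Tpx2 (0.76) did not pass at 2 h. The same held without 2 h replicate 1 for Dctd (1.71), Nomo1 (-1.36) and Tpx2 (0.72), and without 0 h replicate 2 for Dctd (1.26). At 4 h, 1186 genes passed (691 up, 495 down), and 461 without 4 h replicate 1, the library apart on the principal components. Ccnb1 (1.44), Mos (1.01), Plat (0.95), Dazl (0.91), Ccnb3 (0.80) and Cdc20 had passed by then. Magoh (2.58), Cmpk1 (2.29) and Srsf7 (2.22) rose most, and Ergic3 (-1.97), Zp1 (-1.93) and Cenpm (-1.88) fell most. Without 4 h replicate 1, Cdc20 (0.79) and Cenpm (-1.10) did not pass at 4 h, nor did Cenpm without 0 h replicate 1 (-1.04). At 6 h, 2108 genes passed (1102 up, 1006 down), and 1269 without 6 h replicate 1 or 1267 without 6 h replicate 2. Btg4 passed first at 6 h, at 874.9 ± 76.4 against 422.7 ± 52.9 at 0 h. Magoh (3.16), Tex19.1 (2.54) and Obox5 (2.5) rose most, and Cep290 (-2.23), Smc4 (-2.19) and Ubqln4 (-2.16) fell most. The literature list passed camera from 2 h on, with medians of 0.32, 0.62 and 0.95 at 2, 4 and 6 h (adjusted p 0.000355, 6.58e-06 and 4.56e-07) before 1.25 at 8 h. With an estimated correlation the adjusted p was 0.113 at 2 h, 0.0458 at 4 h and 0.0304 at 6 h. The list had 1 member up and 1 down at 2 h (7 and 2 adjusted over the list alone). Ribosomal protein genes had medians of -0.25, -0.50 and -0.95 (adjusted p 0.0112, 0.000707 and 1.79e-06; 0.54, 0.385 and 0.31 with an estimated correlation). Their call was lost without 0 h replicate 1 at 2 h (0.273) and without 4 h replicate 1 at 4 h (0.0858). Proteasome genes had a median of 0.00 at 4 h and -0.48 at 6 h, neither past the list test. Of 19 lists on ribosomes, 11 passed camera at 2 h, 10 at 4 h and 9 at 6 h. With an estimated correlation 0, 2 and 1 did.

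**Figure D4:**
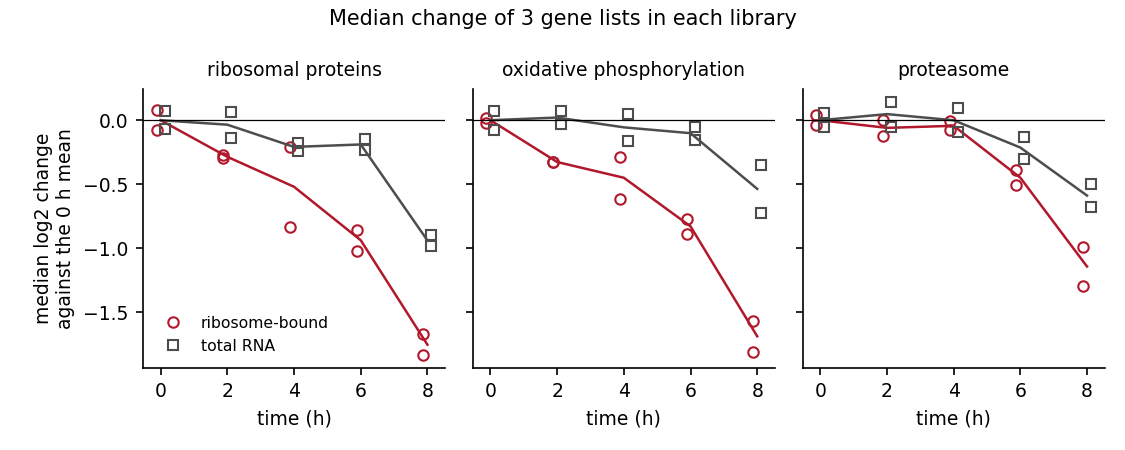
Median log2 change against the 0 h mean (y axis) of ribosomal protein, oxidative phosphorylation and proteasome genes in each library, against hours after release (x axis), for ribosome-bound mRNA and total RNA. Both 8 h libraries lie lowest in each panel; in total RNA the ribosomal protein medians at 8 h are -0.98 and -0.90.

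Neighbouring time points show in which intervals a change on ribosomes passed the test. Ccnb1 and Dazl passed as rises between 2 h and 4 h, oocyte-secreted Oosp3 between 4 h and 6 h, and Btg4 between 6 h and 8 h. In that last interval most calls were falls, among them Park7 and Rps13. Each gene named for these intervals lost its call there without at least 1 of the 4 libraries compared. Between 2 h and 4 h, 55 genes passed (53 up, 2 down), with Cmpk1 (1.47), Fubp3 (1.39) and Tex19.1 (1.34) rising most, Ccnb1 (0.85) and Dazl (0.69) also up, and Ext2 (-1.61) and Sgf29 (-0.93) down. The count was 4 without 2 h replicate 1, 5 without 4 h replicate 1 and 2 without 2 h replicate 2. In each of these fits Ccnb1 (0.86, 0.80 and 0.83) and Tex19.1 (1.45, 1.13 and 1.24) did not pass. Whichever of the 4 libraries was left out, Cmpk1 (1.35 to 1.59), Fubp3 (1.10 to 1.67), Dazl (0.61 to 0.78), Ext2 (-1.82 to -1.39) and Sgf29 (-1.09 to -0.77) did not pass. Between 4 h and 6 h, 5 genes passed, all up, among them Fpgs (1.13), Oosp3 (1.07) and Tcl1 (1.01). None passed without 4 h replicate 1, 6 h replicate 1 or 4 h replicate 2 in limma, and 1 did without 6 h replicate 2; 824 genes had an unadjusted p below 0.05 and voom weights gave 22. Fpgs (0.94 to 1.31), Oosp3 (0.97 to 1.17) and Tcl1 (0.90 to 1.12) did not pass whichever of the 4 was left out. Between 6 h and 8 h, 52 genes passed (7 up, 45 down). Zc3h6 (1.02), Btg4 (0.83) and Omt2b (0.83) rose, and Park7 (-2.39), Rps13 (-2.27) and Cox14 (-1.89) fell most. That count was 3 without 6 h replicate 1, 28 without 8 h replicate 1, 11 without 6 h replicate 2 and 9 without 8 h replicate 2. Without 6 h replicate 1, 6 h replicate 2 or 8 h replicate 2, Btg4 (0.92, 0.74 and 0.75) did not pass, and neither did Park7 (-2.32, -2.46 and -2.07) or Rps13 (-2.30, -2.25 and -2.10). Cox14 was lost without 6 h replicate 1 (-1.64) or 8 h replicate 1 (-1.53), and Zc3h6 (0.94 to 1.10) and Omt2b (0.76 to 0.89) whichever of the 4 was left out.

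Total RNA asks whether the transcripts themselves changed as a share of all RNA measured, and here few genes passed before metaphase I. As values are scaled within each library, a rise or fall common to all transcripts cannot be seen in either RNA kind. At 8 h the lists of ribosomal protein, respiratory chain and proteasome genes fell at the preset correlation, but with an estimated correlation their adjusted p was 0.0976, 0.326 and 0.368. Ccnb1, Mos, Btg4, Dazl and Plat, all up on ribosomes, did not pass in total RNA, although Mos (0.31, adjusted p 0.29) did so after the length and GC correction (0.60, adjusted p 0.0338). Ccnb2 did not pass either (0.78, adjusted p 0.0956), but did after that correction (1.02) and without 8 h replicate 2 (1.19). With the length and GC correction, 301 genes passed at 8 h against 0 h (130 up, 171 down). Of these, 218 were also called in the same direction without it. Without the correction, 314 of 7917 genes passed in limma at 8 h against 0 h, 75 up and 239 down. The count depended on the 0 h libraries, with 52 (6 up, 46 down) without 0 h replicate 1, 161 without 0 h replicate 2 and 195 without 8 h replicate 1. With a mean value of at least 20 and no overlap between groups, the largest falls were Rps4x (-2.67 ± 0.27), Rps9 (-2.55 ± 0.32), the succinate dehydrogenase subunit Sdhd (-2.31 ± 0.21), Setd4 (-2.29 ± 0.24), Vamp8 (-2.26 ± 0.37) and Ndfip2 (-2.25 ± 0.25). Sdhd (ENSMUSG00000000171.4, chromosome 9, 50596357 to 50603812) went from 109 ± 17 to 21.2 ± 0.921. Vamp8 lost its call without 0 h replicate 1 (-1.74); the other 5 kept theirs in each such test. Under the same conditions the largest rises were Ddb2 (1.72 ± 0.38), Pou2f3 (1.42 ± 0.34), Mrpl3 (1.33 ± 0.35), Smco4 (1.28 ± 0.23), Fubp3 (1.23 ± 0.25) and Lonrf2 (1.13 ± 0.30). None kept its call in every such test. Without 0 h replicate 1, Ddb2 (1.28), Pou2f3 (1.2), Mrpl3 (1.35), Fubp3 (1.23) and Lonrf2 (0.99) no longer passed. Without 8 h replicate 1 the same held for Ddb2 (1.32), Pou2f3 (1.42), Mrpl3 (0.69) and Lonrf2 (1.01), and without 0 h replicate 2 for Smco4 (0.98), Mrpl3 (1.30) and Lonrf2 (1.27); Lonrf2 also fell short without 8 h replicate 2 (1.25).

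Of the gene lists in total RNA, 6 of 20 passed, and none did with an estimated correlation. Ribosomal protein genes fell in 21 of 55 cases (30 adjusted over the list alone), with a median of -0.90, a camera adjusted p of 5.09e-20 and an adjusted p of 0.0976 with an estimated correlation. Oxidative phosphorylation genes fell in 10 of 52 (16 adjusted over the list alone; median -0.65, adjusted p 6.53e-09, and 0.326 with an estimated correlation), including Ndufa9 (-1.93). Proteasome genes fell in 11 of 31 and rose in 1 (16 and 3 adjusted over the list alone; median -0.58, adjusted p 1.42e-06, and 0.368 with an estimated correlation), including Psmc2 (-1.35). Initiation and elongation factors fell in 4 of 49 (6 adjusted over the list alone; adjusted p 0.0439, and 0.368 with an estimated correlation), including Eif6 (-1.81) and Eef1d (-1.67). Their list call was lost without 0 h replicate 2 (adjusted p 0.141) and without 8 h replicate 2 (adjusted p 0.267). Stress genes had Dnajb1 (-1.30) and Ddit3 (-1.95) down among 6 (3 adjusted over the list alone; list adjusted p 0.00787, and 0.335 with an estimated correlation). Ddit3 lost its call without 0 h replicate 1 (-1.86), 8 h replicate 1 (-1.89) or 0 h replicate 2 (-2.05), and after the length and GC correction (-1.59). Mitochondrially encoded transcripts rose as a list with no single gene past the threshold (adjusted p 0.0439, and 0.626 with an estimated correlation). That call ended without 8 h replicate 1 (0.191), 0 h replicate 2 (0.24) or 8 h replicate 2 (0.0613). The literature list did not move (median 0.08, adjusted p 0.803), with 1 up and 2 down (3 and 4 adjusted over the list alone). Among single genes, Tacc3 (-1.13), Rpa2 (-1.36), Cnot8 (-1.91) and Zar1l (-1.57) fell and kept their calls without any 1 library. Cdc20 rose (0.87, adjusted p 0.039) but did not pass without 0 h replicate 1 (0.90), 8 h replicate 1 (0.93), 0 h replicate 2 (0.84) or 8 h replicate 2 (0.81). For zona and granulosa genes the sign of the median differed from that of the test; the granulosa list had an adjusted p of 0.848, and 0.00725 without 8 h replicate 1.

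Before 8 h few single genes passed in total RNA, and no panel gene did at 2, 4 or 6 h. Some lists passed camera at the preset correlation, and none did with an estimated correlation. In limma 0 genes passed at 2 h (226 at an unadjusted p below 0.05) and 0 at 4 h (347), and voom weights also gave 0 at both; 1 gene passed at 4 h without 4 h replicate 1. At 6 h, 16 genes passed (14 up, 2 down), with Pou2f3 (2.16), Omt2b (1.33) and Omt2a (1.28) rising most and Eef1d (-1.23) and Cpsf4l (-1.02) down. That count was 0 without 0 h replicate 1 and 0 without 0 h replicate 2 (613 genes at an unadjusted p below 0.05 with all libraries, and 18 calls with voom weights), and 1 without 6 h replicate 2. In those 3 fits Pou2f3 (1.94, 2.39 and 1.80), Omt2b (1.47, 1.19 and 1.08) and Omt2a (1.42, 1.14 and 1.06) did not pass, and Eef1d (-1.37 to -1.09) and Cpsf4l (-1.20 to -0.85) did not whichever of the 4 libraries was left out. Of 20 lists, 1 passed at 2 h, 5 at 4 h and 3 at 6 h. Ribosomal protein genes were lower as a list at 4 h (median -0.19, adjusted p 0.0071, and 0.507 with an estimated correlation) and at 6 h (median -0.14, adjusted p 0.00647, and 0.645 with an estimated correlation). No single member passed at either time, or 0 at 4 h and 2 at 6 h adjusted over the list alone. The call was lost without 0 h replicate 1 at 4 h (0.1) and at 6 h (0.0778), and without 4 h replicate 1 at 4 h (0.158). Proteasome genes passed at 6 h (median -0.36, adjusted p 0.0255, and 0.696 with an estimated correlation; no member past the threshold, or 2 up and 3 down adjusted over the list alone), but not without 0 h replicate 1 (0.265) or 6 h replicate 2 (0.19). Mitochondrially encoded transcripts were lower at 2 h (median -0.18, adjusted p 0.00128, and 0.728 with an estimated correlation) and 4 h (median -0.13, adjusted p 0.0071, and 0.507 with an estimated correlation). Their call was lost without 0 h replicate 1 (0.0631 at 2 h, 0.1 at 4 h), without 2 h replicate 2 (0.849) and without 4 h replicate 2 (0.449). Reticulum genes were higher at 6 h (median 0.14, adjusted p 0.0115, and 0.63 with an estimated correlation), but not without 0 h replicate 1 (0.148) or 6 h replicate 2 (0.19). At 4 h deadenylation, reticulum and literature list genes were higher (each adjusted p 0.0474, and 0.507 with an estimated correlation), a call that each lost without any 1 of the 4 libraries compared.

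Setting ribosome-bound mRNA against total RNA asks which transcripts changed on ribosomes by more or less than in total RNA. Ccnb1, Plat, Btg4, Mos, Dazl and Tpx2 rose on ribosomes beyond total RNA. As lists at the preset correlation, spindle genes rose beyond total RNA and respiratory chain genes fell, but with an estimated correlation the adjusted p was 0.0802 and 0.094. The test is the difference between the ribosome-bound and the total RNA change, over all 20 libraries and 7346 genes. At 8 h against 0 h, 1543 genes passed, 850 up and 693 down. Plat (2.58 ± 0.22, adjusted p 3.8e-08), Ccnb1 (2.23 ± 0.20, adjusted p 4.4e-08), Btg4 (1.80 ± 0.19), Mos (1.44 ± 0.23), Dazl (1.44 ± 0.21) and Tpx2 (0.79 ± 0.18) rose. Cdc20 (0.41, adjusted p 0.39), Wee2 (0.37, adjusted p 0.13), Ccnb3 (0.51, adjusted p 0.14), Ccnb2 (-0.72, adjusted p 0.21) and Cpeb1 (-0.30, adjusted p 0.23) did not pass. Among genes with a mean value of at least 20 and no overlap between groups, the largest rises were Pstpip2 (3.25 ± 0.52), the deadenylase Cnot8 (3.22 ± 0.37), Zfp280d (3.19 ± 0.32), Ndfip2 (2.90 ± 0.36), Slc35b3 (2.83 ± 0.51) and Plat. Among the same genes the largest falls were Ubqln4 (-2.53 ± 0.49), Map1lc3a (-2.35 ± 0.53), the cytochrome oxidase subunit Cox6c (-2.30 ± 0.37), Slc12a7 (-2.30 ± 0.51), Ogdh (-2.25 ± 0.24) and Gphn (-2.23 ± 0.45). Cnot8 (ENSMUSG00000020515.13, chromosome 11, 58104153 to 58118594) went from 37.8 ± 0.79 to 95.4 ± 10.5 on ribosomes and from 57.4 ± 3.37 to 15.3 ± 6.97 in total RNA. These tables were scaled separately, so each value is set only against others of its own table. After the length and GC correction Dazl stood at 0.84.

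By list, 8 of 19 passed beyond total RNA at 2 h, 11 at 4 h and 11 at 6 h, and 3 did at each time with an estimated correlation. At 8 h, 12 of 19 passed, and only the literature list did so with an estimated correlation. It had 16 of 24 genes up and 2 down, the same adjusted over the list alone, with a median of 1.13, a camera adjusted p of 5.54e-09 and an adjusted p of 0.000708 with an estimated correlation. Spindle genes (12 of 28 up, 1 down; 13 and 2 adjusted over the list alone; adjusted p 0.00305) and kinetochore genes (9 of 28 up, 2 down; 9 and 3 adjusted over the list alone; adjusted p 0.0125) rose. Both had an adjusted p of 0.0802 with an estimated correlation. Kif18a (2.15), Anln (1.68), Ndc80 (2.13) and Bub1b (1.31) led them. Cohesin and condensin rose (5 of 22 up, 2 down; 6 and 2 adjusted over the list alone; adjusted p 0.0323), with Ncapg2 (2.23) and Wapl (1.54) up and Smc4 (-2.10) down. With an estimated correlation its adjusted p was 0.257, and without the ribosome-bound 0 h replicate 2 it was 0.0683. Deadenylation genes rose (6 of 24 up, 4 down; 8 and 5 adjusted over the list alone; adjusted p 0.0444). With an estimated correlation that adjusted p was 0.094, and without the ribosome-bound 0 h replicate 2 it was 0.0687. Oxidative phosphorylation genes fell in 14 of 52 (21 adjusted over the list alone; median -1.02, adjusted p 1.18e-06, and 0.094 with an estimated correlation). Ribosomal protein genes fell in 7 of 47, but in 0 adjusted over the list alone in limma (median -0.77, camera adjusted p 0.000377, and an adjusted p of 0.302 with an estimated correlation). Factor genes fell in 11 of 49 and rose in 2 (13 and 2 adjusted over the list alone; adjusted p 0.00305, and 0.0802 with an estimated correlation).

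The remaining lists that passed beyond total RNA were close to the threshold. Endoplasmic reticulum genes (10 of 32 down, 3 up; 11 and 3 adjusted over the list alone), with Calr at -2.13, had an adjusted p of 0.0266, and 0.257 with an estimated correlation. At the preset correlation and without the ribosome-bound 0 h replicate 2 it was 0.0945. Proteasome genes (5 of 31 down, 2 up; 6 and 3 adjusted over the list alone), with Psmd2 at -1.66, had an adjusted p of 0.0489, and 0.365 with an estimated correlation. At the preset correlation it was 0.165 without total RNA 8 h replicate 1, 0.0945 without ribosome-bound 0 h replicate 2, 0.117 without total RNA 0 h replicate 2 and 0.103 without ribosome-bound 8 h replicate 2. Maternal-effect genes (12 of 32 down, 5 up; 14 and 5 adjusted over the list alone), with Dnmt3l at -2.09 and Rfpl4 at 2.07, had an adjusted p of 0.0447, and 0.302 with an estimated correlation. At the preset correlation it was 0.193 without ribosome-bound 0 h replicate 1, 0.0714 without ribosome-bound 8 h replicate 1, 0.0616 without total RNA 8 h replicate 1 and 0.0513 without total RNA 0 h replicate 2. Chromatin genes (4 of 25 up, 3 down; 6 and 3 adjusted over the list alone), with Eed at 1.85 and Slbp at 1.67, had an adjusted p of 0.0499, and 0.257 with an estimated correlation. At the preset correlation it was 0.18 without ribosome-bound 0 h replicate 1, 0.0861 without total RNA 0 h replicate 2, 0.103 without ribosome-bound 8 h replicate 2 and 0.077 without total RNA 8 h replicate 2. Replication licensing genes did not pass, and their median (-0.26) and test differed in sign.

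The number of genes changed on ribosomes beyond total RNA grew over the time course. Eif5b had fallen by 2 h, Ccnb1 had risen by 4 h and Plat by 6 h, calls that held without any 1 library. Those of Slbp and of Izumo1r, the egg's sperm receptor, at 2 h, of Mos, Dazl and Tpx2 at 4 h and of Btg4 at 6 h did not. At 2 h, 7 genes passed (1 up, 6 down), among them Slbp (0.94), Eif5b (-1.51), Izumo1r (-1.40) and Nrd1 (-1.35). The count was 23 without ribosome-bound 0 h replicate 1, 3 without total RNA 0 h replicate 1, 1 without ribosome-bound 2 h replicate 1, 4 without total RNA 2 h replicate 1 and 2 without total RNA 0 h replicate 2. Slbp did not pass without ribosome-bound 0 h replicate 2 (0.90), 2 h replicate 1 (0.91) or 2 h replicate 2 (0.96), or without total RNA 0 h replicate 1 (0.87), 0 h replicate 2 (1.00) or 2 h replicate 1 (0.78). Izumo1r did not without ribosome-bound 2 h replicate 1 (-1.44) or 2 h replicate 2 (-1.36), or total RNA 0 h replicate 1 (-1.33), 0 h replicate 2 (-1.47) or 2 h replicate 1 (-1.17). Nrd1 passed without ribosome-bound 0 h replicate 2 and in none of the other 7 such fits (-1.41 to -1.11). At 4 h, 375 genes passed (227 up, 148 down). Without 1 library this was 151 (total RNA 0 h replicate 1), 216 (ribosome-bound 4 h replicate 1), 202 (total RNA 4 h replicate 1), 210 (total RNA 0 h replicate 2) or 186 (total RNA 4 h replicate 2). Ccnb1 (1.37), Mos (0.91), Dazl (0.77) and Tpx2 (0.76) were up. The heparanase gene Hpse (2.13), Obox7 (2.08) and Pstpip2 (2.01) rose most, and Ubqln4 (-2.29), Pdk1 (-1.93) and Rpn2 (-1.87) fell most. Of these, 6 lost the call without some library. Without ribosome-bound 0 h replicate 1 they were Pstpip2 (1.69) and Pdk1 (-1.86), and without ribosome-bound 0 h replicate 2 Mos (0.72), Dazl (0.73) and Pdk1 (-1.99). Without ribosome-bound 4 h replicate 1 they were Tpx2 (0.61), Hpse (1.75), Pstpip2 (1.77) and Pdk1 (-1.29), and without ribosome-bound 4 h replicate 2 Mos (0.74) and Dazl (0.69). Without total RNA 0 h replicate 1 they were Dazl (0.79), Tpx2 (0.69), Hpse (2.00) and Pdk1 (-1.54), and without total RNA 0 h replicate 2 Mos (0.83), Dazl (0.75) and Pstpip2 (1.67). Without total RNA 4 h replicate 1 they were Dazl (0.84), Pstpip2 (1.90) and Pdk1 (-2), and without total RNA 4 h replicate 2 Mos (0.85), Dazl (0.70), Tpx2 (0.71), Hpse (1.93), Pstpip2 (2.12) and Pdk1 (-1.85). At 6 h, 860 genes passed (539 up, 321 down), and 524 without total RNA 0 h replicate 1. Cenpc1 (2.63), Prr23a3 (2.36) and Pstpip2 (2.34) rose most, and Pou2f3 (-2.99), Ubqln4 (-2.77) and Rpn2 (-2.34) fell most, with Plat at 1.76 and Btg4 at 0.78. Btg4 did not pass without total RNA 6 h replicate 1 (0.65). Ccnb3 also rose beyond total RNA, by 0.98 at 4 h and 1.09 at 6 h, though it did not pass at 8 h. Its 4 h call was lost without ribosome-bound 0 h replicate 2 or any 1 of the total RNA libraries compared. The 6 h call held without any 1 library.

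Genes that moved the same way in both RNA kinds at 8 h were more frequent than independence would give. Of the 7346 genes in both tables, 53 rose in both (15.4 by independence) and 174 fell in both (49.5), whereas 15 rose on ribosomes and fell in total RNA (46.8). A further 5 fell on ribosomes and rose in total RNA (16.3). Without total RNA 0 h replicate 1 these 4 counts were 6 (1.23), 34 (9.78), 5 (9.23) and 0 (1.3), and without its 0 h replicate 2 they were 15 (5.13), 100 (28.7), 11 (27.1) and 0 (5.43). Without total RNA 8 h replicate 1 they were 13 (3.69), 133 (37.8), 11 (35.7) and 3 (3.91), and without its 8 h replicate 2 64 (25.4), 153 (56.1), 20 (52.9) and 11 (26.9). Without ribosome-bound 0 h replicate 1 the last count was 3 (13.7), and without ribosome-bound 8 h replicate 2 the last 2 were 10 (32.6) and 2 (11). Across genes, which are not independent replicates, the changes correlated with a Pearson r of 0.392 and a Spearman rho of 0.33. Rps4x and Sdhd fell in both, and Fubp3 and Obox5 rose in both. In total RNA, Fubp3 (1.23) and Obox5 (0.72) did not pass without 0 h replicate 1, nor did Obox5 without 8 h replicate 1 (0.51) or 0 h replicate 2 (0.59).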

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

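The difference between the ribosome-bound and the total RNA change was a planned test; the opposite-direction counts, and the length and GC, carry-over, matched-set and single-library tests below, were chosen after the calls they examine were seen, though each bound was set before its own value was known.

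What set these results apart is that the change over time differed between the 2 RNA kinds by an interaction test: 7 genes at 2 h, 375 at 4 h, 860 at 6 h and 1543 at 8 h, and 12 gene lists at 8 h, of which 1, the literature list, also passed with an estimated correlation. The values below are log2 changes on ribosomes beyond total RNA at 8 h. Among genes with a mean value of at least 20 and no overlap between groups, the largest were Pstpip2 3.25, Cnot8 3.22, Zfp280d 3.19, Ndfip2 2.90, Slc35b3 2.83 and Plat 2.58 upward, and Ubqln4 -2.53, Map1lc3a -2.35, Cox6c -2.30, Slc12a7 -2.30, Ogdh -2.25 and Gphn -2.23 downward. Among M-phase and anaphase-promoting genes they were Ccnb1 2.23, Mos 1.44, Mapk3 -1.5, Plk1 -0.83, Cdc27 1.89, Fbxo43 2.20, Fzr1 -1.15 and Anapc5 -0.83. In the spindle and kinetochore lists they were Tpx2 0.79, Ndc80 2.13, Bub1b 1.31, Birc5 -1.35, Zwilch -1.75, Anln 1.68, Kif18a 2.15 and Tacc3 -0.89. For chromosome and replication genes the values were Ncapg2 2.23, Wapl 1.54, Smc4 -2.10, Pttg1 -0.96, Mcm4 1.44, Orc6 1.99, Rpa1 -1.03 and Rpa2 -1.04. For mRNA regulators they were Btg4 1.80, Dazl 1.44, Pan2 1.99, Cnot1 -1.13, Cnot10 -1.46, Cpeb4 1.19, Pabpc1l -1.90, Ybx2 -1.45 and Zar1 -1.18.

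Genes of protein synthesis, respiration and breakdown had Eif2b1 0.89, Eif2a 1.45, Eif3c -1.11, Eif1ax -1.65, Rpl5 -0.88, Rps14 -1.89, Ndufa5 -2.64, Psma2 0.95, Psma1 1.56, Psmd2 -1.66 and Psma6 -1.29. Reticulum and egg surface genes had Ssr3 1.88, Dnajc3 0.92, Calr -2.13, Pdia3 -1.67, Oosp1 1.88, Zp2 -1.77 and Zp1 -1.73. Maternal-effect and chromatin genes had Rfpl4 2.07, Obox5 1.97, Uhrf1 -1.44, Dnmt3l -2.09, Slbp 1.67, Eed 1.85, Kdm1b -1.30 and Smarca4 -1.01. The marker, stress and mitochondrial lists had Serpine2 0.96, Dusp1 1.5, Hsph1 -0.73 and mt-Rnr2 1.69.

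Of all these genes, 12 lost the call without some library. Without ribosome-bound 0 h replicate 1 these were Fzr1 (-0.97), Cnot10 (-1.20) and Rps14 (-1.87); without ribosome-bound 0 h replicate 2, Anapc5 (-0.74), Dusp1 (0.69), Psma6 (-1.19), mt-Rnr2 (1.33), Zwilch (-1.41), Rpa2 (-0.71), Eif2a (0.89) and Psma1 (1.09). Without ribosome-bound 8 h replicate 1 they were Psma6 (-1.05) and mt-Rnr2 (1.13), and without ribosome-bound 8 h replicate 2 Rps14 (-1.75), Anapc5 (-0.75), Dusp1 (1.45), Rpa2 (-0.85), Psma1 (1.32) and Rpl5 (-0.79). Without total RNA 0 h replicate 1 they were Rps14 (-1.92), Anapc5 (-0.67) and Dusp1 (1.17), and without total RNA 0 h replicate 2 Fzr1 (-1.02), Cnot10 (-1.27), Rps14 (-1.87), Psma6 (-1.10), Rpa2 (-0.98), Eif2a (1.22) and Psma1 (1.54). Without total RNA 8 h replicate 1 they were Fzr1 (-1.11), Rps14 (-1.77), Anapc5 (-0.60), Psma6 (-1.09) and Zwilch (-1.41), and without total RNA 8 h replicate 2 Dusp1 (1.29), mt-Rnr2 (1.52) and Rpl5 (-0.69).

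After the length and GC correction Fzr1 (-0.78), Rps14 (-1.15) and Psma2 (0.47) no longer passed. With a pseudocount of 5 the calls of Rps14 (-0.98, limma adjusted p 0.112) and Psma6 (limma adjusted p 0.0528) ended.

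At 8 h, 15 genes rose on ribosomes and fell in total RNA: Tmem68, Cnot8, Zfp280d, E330021D16Rik, Ndfip2, Gm5946, Tcea1, Casp8ap2, N4bp2, Mapk6, Eed, Ern1, Dab2, Alg10b and Dazap2. The reverse held for 5 genes, Furin, Camsap3, Wbp11, Copz2 and Prmt5. Without total RNA 0 h replicate 1 the counts were 5 and 0; those without other libraries stand with the shared changes. All 20 also passed the interaction test, which adds no support. That test takes the difference of the same changes by which these genes were chosen. Cnot8 rose by 1.31 on ribosomes and stood at -1.91 in total RNA, N4bp2 at 1.12 and -1.07, Zfp280d at 1.92 and -1.27, and Prmt5 at -1.47 and 1.65. For 15 of the 20 the total RNA call was lost without its 0 h replicate 1; Cnot8, Ndfip2, Casp8ap2, N4bp2 and Mapk6 passed without that library too.

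The pattern of 1543 genes with a ribosome-bound change beyond total RNA at 8 h was weighed against transcript length or GC bias between libraries. Of these genes, 1508 had a known length and GC content. Values of the others could not be corrected, but these genes stay in the share below. After each library was corrected for smooth trends on both, 71.4% of the genes (1101; exact 95% interval 69.0% to 73.6%) were still called in the same direction, above the bound set beforehand for excluding such bias as the whole cause. The correction ended 442 calls, whose median absolute log2 change went from 1.08 to 0.72 with a median standard error of 0.33 before and 0.32 after, so they ended because the change shrank and not because the error grew. The change correlated across genes with GC content (r -0.319), so a part of it may be such bias, or the correction may have removed a biological part tied to base composition.

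A change in the share of unbound RNA carried over in the pull-down would move nearly all called genes towards the median ratio of ribosome-bound to total RNA, or nearly all away from it. Of the 1543 genes, 42.1% moved away (exact 95% interval 39.6% to 44.6%; 52.0% of genes up and 29.9% of genes down), which argues against such a change as the whole cause. The mitochondrially encoded share on ribosomes, as a percent of that in total RNA, went from 3.73% at 0 h to 7.67% at 8 h, the direction of more carry-over, with ribosome-bound shares of 0.118% and 0.0819% in the 0 h replicates and 0.272% and 0.126% in those at 8 h. What stays open is carry-over as a part of the cause, the recovery of tail-length classes, if poly(A) RNA was selected, and the biological explanation that the design names, a change in translation between prophase I and metaphase I, which could account for these genes and was not separated from tail length here.

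Lower ribosomal protein, oxidative phosphorylation and proteasome transcripts in total RNA at 8 h (138 genes, median -0.73) passed as lists at the preset correlation, but none of the 3 did with an estimated correlation (adjusted p 0.0976, 0.326 and 0.368). They were weighed against a loss of short transcripts, since these genes have a median length of 1014.5 bases against 3363.5 for all. Of 1000 random sets of other genes matched on length and level, 0% had a median as low (matched median -0.11, lowest -0.30), so a length effect shared with other genes is not the whole cause. A single deviating 8 h library is also argued against: the 3 lists' median was -0.59 (95% interval over genes -0.75 to -0.40) in replicate 1 and -0.80 (-0.95 to -0.72) in replicate 2. These intervals treat genes as independent and do not measure the spread between libraries. Both medians were taken against the same 0 h mean, so a deviating 0 h library would move both. Decay of these transcripts, or shorter tails if poly(A) RNA was selected, may underlie the fall and was not tested; reads shared with pseudogenes stay open for ribosomal protein genes.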

How the results depend on the processing

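Voom weights, the minimum mean value of 20, the length and GC correction, the estimated correlation for lists before 8 h, and the fits without each library for lists and named genes before 8 h and for the genes moving in both RNA kinds were chosen after the data were seen; the other alternatives were planned. Where a count moved by over 1.5 times the cause was not tested, except that a 2-fold threshold can only lower a count and that fits with fewer libraries have fewer degrees of freedom. Pseudocounts of 0.25 and 5 and centring on library medians left all counts of genes and lists within 1.5 times the main value, but a pseudocount of 5 ended the calls of Rps14 and Psma6 beyond total RNA. No filter and a minimum of 10 removed 0 or 1 gene and so say nothing. edgeR and DESeq2 were not run.

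Without the mean-variance trend, ribosome-bound calls were 0 at 2 h and 661 at 4 h, and 0 for each of the 3 neighbouring steps. Total RNA calls were 0 at 6 h and 158 at 8 h, and calls beyond total RNA 0 at 2 h and 154 at 4 h. These are limma counts; with the trend the unadjusted p was below 0.05 for 1295 genes on ribosomes at 2 h, 613 in total RNA at 6 h, 784, 824 and 984 in the steps, and 766 beyond total RNA at 2 h, where voom gave 99, 18, 43, 22, 31 and 14.

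A 2-fold threshold gave 35, 507, 1019 and 1866 ribosome-bound genes at 2, 4, 6 and 8 h, 8 and 199 in total RNA at 6 and 8 h, 17, 3 and 28 in the steps, and 219 and 543 beyond total RNA at 4 and 6 h. Fits with only the compared times gave 38 and 572 on ribosomes at 2 and 4 h, 2 and 164 in total RNA at 4 and 8 h, 95, 19 and 92 in the steps, and 162 beyond total RNA at 4 h. Voom gave 208 in total RNA at 8 h, 22 from 4 to 6 h, 31 from 6 to 8 h and 14 beyond total RNA at 2 h. A mean value of at least 20 gave 173 on ribosomes at 2 h, 13 from 4 to 6 h, 101 from 6 to 8 h and 15 beyond total RNA at 2 h. An estimated correlation left 3 lists on ribosomes, 0 in total RNA and 1 beyond total RNA.

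Replicate letters showed little sign of pairing the samples. Weak correlations cannot exclude pairing, and the labels do not state it. Residuals with the same letter correlated between -0.109 and 0.0511 within ribosome-bound libraries (0 of 10 pairs over 0.1). The range was -0.0558 to 0.134 within total RNA (1 of 10) and -0.0837 to 0.0363 across kinds at the same time (0 of 5). Across kinds at different times it was -0.108 to 0.166. A block on the letter gave 57 ribosome-bound genes at 2 h, 34 from 2 to 4 h and 2 from 4 to 6 h, with the other counts within 1.5 times. Beyond total RNA 9 lists passed with it, without deadenylation (adjusted p 0.0977), maternal-effect (0.0962) and chromatin genes (0.0759).

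Leaving out each library in turn, with the lone library assumed to vary like the other groups, gave 15 to 171 ribosome-bound genes at 2 h, 461 to 1120 at 4 h, 1267 to 1752 at 6 h and 2159 to 2786 at 8 h. In total RNA it gave 0 to 0 at 2 h, 0 to 1 at 4 h, 0 to 11 at 6 h and 52 to 414 at 8 h. The steps gave 2 to 47, 0 to 1 and 3 to 28. Beyond total RNA the counts were 1 to 23, 151 to 426, 524 to 856 and 1084 to 1439. Lists past the threshold numbered 10 to 13 on ribosomes, 4 to 6 in total RNA and 8 to 12 beyond it. The libraries behind these moves are named with the results.

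Of the named genes on ribosomes, 983 of 1008 values over 84 genes and all alternatives kept direction and side of the threshold, 23 lost the threshold and 2 reversed. In total RNA 493 of 612 values over 51 genes did, 108 lost it, 4 gained it and 7 reversed; the gains were Mos (0.60, after the length and GC correction) and Ccnb2 (1.02 after it, 0.78 with the replicate block and 1.19 without 8 h replicate 2). Beyond total RNA 1229 of 1280 over 80 genes did and 51 lost it. The reversals, all of genes with no call, were Ccnb2 on ribosomes and 4 panel genes in total RNA. Without 1 library Ccnb2 ran from -0.11 (8 h replicate 1) to 0.23 and was also below 0 without 0 h replicate 1. In total RNA Ccnb3 stood at -0.058 after the length and GC correction, and ran from -0.039 (8 h replicate 1) to 0.10, below 0 also without 0 h replicate 1. Wee2 ran from -0.016 (0 h replicate 1) to 0.18 and Btg4 from -0.053 (8 h replicate 1) to 0.21. Tpx2 ran from -0.026 (8 h replicate 2) to 0.13, below 0 also without 0 h replicate 2.

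Beyond the genes already given with a corrected value, the length and GC correction moved the change by over 1.5 times for Mapk3 (-0.79), Cdc27 (1.2), Birc5 (-0.68), Ybx2 (-0.86), Psma2 (0.86), Npm2 (-1.04), Zar1 (-0.78), Dnajc3 (0.79), Rps27l (2.80) and Dazl (1.18) on ribosomes, and there ended the calls of Tubg1 (-0.56) and Pttg1 (-0.05) besides Wee2 and Ccnb3. Beyond total RNA it did so for Plk1 (-0.53), Zar1 (-0.71) and Dnajc3 (0.60), and ended the calls of Fzr1 (-0.78), Rps14 (-1.15) and Psma2 (0.47). In total RNA it ended those of Spc25 (-0.96), Zp3 (-0.34), Npm2 (-0.48), Hells (0.71), Eed (-0.58), Aurka (-0.47) and Ddit3. The effect of depth was not tested; a value of 10 stood for 282 to 533 inferred reads, and genes below the tables' minimum were not seen.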

Other observations

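The test here was chosen from knowledge of oocyte translation after the calls were seen; its bounds were set before its value was known.

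The hypothesis was that a cytoplasmic polyadenylation element (TTTTAT or TTTTAAT in the last 150 bases of the 3' UTR) goes with a gain of ribosomes beyond total RNA at 8 h. Of 6575 genes with a 3' UTR long enough to search, 1835 had the element. It was present in 49.3% of genes called up, 13.8% of genes called down and 26.3% of the others. Because the element is rich in A and T, genes were compared within 25 strata of AT content and 3' UTR length. There, genes with the element changed by 0.30 more on the log2 scale (95% interval 0.25 to 0.34; permutation p 1e-04, the smallest that 10000 permutations can give). The reversed motif gave 0.11 (0.07 to 0.16), with the same permutation p of 1e-04. That p therefore does not separate the element from base composition, and only the size of the difference sets them apart. These intervals and permutation p-values are taken over genes, which are not independent replicates, and do not measure the spread between samples.

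The stratified difference was 0.08 at 2 h, 0.13 at 4 h and 0.22 at 6 h, and that of the reversed motif 0.04, 0.06 and 0.08. The element's difference exceeded that of the reversed motif at each time. A contribution of the element to ribosome loading stays a hypothesis. The 0.30 at 8 h includes any part shared with the reversed motif (0.11). The strata do not remove every tie between base composition and library recovery, and a longer tail on these transcripts could raise recovery in poly(A)-selected libraries.

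Of the other-cell markers in total RNA, Serpine2 rose at 8 h against 0 h (0.78, limma adjusted p 0.00498), but not past the threshold without 0 h replicate 2 (0.65). Among those that did not pass, the endothelial marker Pecam1 stood at 125 ± 16.1 (SD, n = 2) at 0 h and 136.5 ± 3.77 at 8 h (limma adjusted p 0.717), and the granulosa marker Nr5a2 at 93.6 ± 4.87 and 79.2 ± 35.6 (limma adjusted p 0.512). Not all granulosa markers were steady between the 8 h replicates. The SD exceeded the mean at 8 h for Gja1 (7.31 ± 2.32 at 0 h, 16.99 ± 24.03 at 8 h) and Inha (2.82 ± 0.71, 6.26 ± 8.85). The same held for Inhba (8.37 ± 2.83, 4.83 ± 5.1). It stayed below the mean for Fshr (11.89 ± 3.75 at 8 h), Cyp19a1 (49.35 ± 0.48) and Col4a2 (15.45 ± 8.52). Pecam1 and Nr5a2 were also listed in the ribosome-bound table. There Pecam1 stood at 138.4 ± 19.6 at 0 h and 114.0 ± 32.4 at 8 h, and Nr5a2 at 48.4 ± 15.1 and 57.3 ± 5.35. Their presence in total RNA therefore does not by itself point to other cells.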
